A study of Homo sapiens with 36 samples.

How the data were processed

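RNA levels were measured on 36 Affymetrix HG-U95Av2 arrays, each hybridized with RNA of human bronchial epithelial cells grown in primary culture. Per the labels, total RNA was isolated with an RNeasy Mini Kit and a Qiashredder column, and 10 micrograms were turned into labelled target by the maker's standard procedure. Per the labels, the values deposited for each array are signal intensities on a linear scale, 1 per probe set. The scanner settings and the software that reduced probes to probe sets were not given in the sources used here. The deposited table held 12625 probe sets, of which 67 were controls, and 21.2% of its values lay below 0. Every deposited array had a mean of about 100 after trimming 2% of values at each end, so the authors' scaling of the intensities was kept. For an array, the number of samples rather than a read depth limits the precision.

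Values below 0 were set to 0, 32 was added, and the log2 was taken. The plan written before the data were examined had not foreseen values below 0, so this floor was added to it. On this scale the lowest value is 5, and changes of genes near that floor are understated. Of the probe sets, 10934 carried 1 gene symbol, 545 carried several and 1070 carried none. The single symbols of 9 probe sets matched no human gene by identifier. Each gene was represented by 1 probe set, the one of the highest mean over all arrays, preferring probe sets not marked as cross-hybridizing. XIST and genes of the Y chromosome were left out. The dimmest 40% of probe sets were left out before 1 was chosen per gene, which put the lowest mean signal kept at 13.8 and left 5503 of 8203 genes. Among the values of these genes, 1.55% lay below 0. For 949 genes over 1 probe set passed the filter. No genome coordinates were used.

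The labels gave 8 groups of treatment and time. Cells received control medium, dexamethasone at 100 nM, interferon gamma (IFN-γ) at 300 units, or both. Each treatment had 4 arrays at 8 h, numbered 1 to 4, and 5 arrays at 24 h, numbered 4 to 8. The labels do not say whether the numbers stand for separate donors or cultures, so every p-value measures the spread between these samples, part of which may be technical. Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes in 1 fit over all 36 arrays, with 28 residual and 5.18 prior degrees of freedom. A gene was called changed at an adjusted p under 0.05 (Benjamini-Hochberg over the 5503 genes of a comparison). The 9 comparisons were IFN-γ against control, dexamethasone against control and both against IFN-γ at each time, the interaction of both treatments at each time, and the IFN-γ response at 24 h against that at 8 h. Differences are log2 values with the standard error of the limma fit. Tests were two-sided.

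Before the data were examined, 26 gene lists were written. They covered JAK-STAT signalling, class I and class II antigen presentation, interferon-induced GTPases, antiviral genes, lymphocyte-attracting chemokines, neutrophil chemokines with NF-κB inflammatory genes, eicosanoid metabolism, tryptophan, nitric oxide and oxidant enzymes, apoptosis, complement, glucocorticoid receptor targets, metallothioneins, ion and water transport, matrix and proteases, cell cycle, cholesterol synthesis, heat shock and immediate early genes, ribosomal proteins, squamous differentiation, and markers of basal, secretory, leukocyte, fibroblast, ciliated and endothelial cells. Lists with at least 5 genes tested were compared by camera with a preset correlation of 0.01 between genes, adjusted over the lists within each comparison. Camera with a correlation estimated from the data, and fry, were run beside it. Members were counted at the adjusted p over all genes and again with the adjustment over the list alone.

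The genes named were chosen by a rule set before the data were examined. It took the 10 largest rises and the 10 largest falls among called genes whose difference had the same sign in every replicate number, or 5 each way for the interactions and the time comparison. It added up to 4 members of each list with the largest change, and a fixed set of IFN-γ and glucocorticoid genes. The effect of dexamethasone on IFN-γ-induced genes was the median difference between both treatments and IFN-γ alone, over genes raised at least 2-fold by IFN-γ at the other time, so that no array both chose and measured a gene.

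The method was tested on simulated data with the spread of the real arrays. Each gene was drawn independently, so the correlation between genes in the real arrays was left out. For IFN-γ against control over 5503 genes at 8 h, 50.7% of 67 genes given a log2 change of 0.5 were recovered, 92.5% of 67 at 1 and 100% of 66 at 2. At 24 h the shares were 53.7%, 97% and 100%. False calls made up 4.14% of calls at 8 h and 5.11% at 24 h. A cell cycle list lowered by 0.3 was called at both times by camera (adjusted p = 1.5e-17 and 8.8e-29), and 0 of the 23 other lists were. Because the simulated genes were independent, this does not show how often lists of correlated genes are called falsely.

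The alternatives planned before the data were examined were quantile normalization, offsets of 1 and 100, no filter and a filter of 60%, all probe sets, the replicate number as a fixed or random block, arrays of 1 time point only, array weights, a trended and robust variance prior, a 2-fold threshold and leaving out each array in turn. Added after the data were seen were a floor of 20 without an offset, leaving out 2 arrays at 8 h with high ratios of 3' to 5' ACTB signal, the 24 h array set as a block, fits within each 24 h set, and a list of NRF2 targets. The camera count with an estimated correlation was tabulated as an alternative at the same stage. A further reference for the count of lists, in which whole arrays of deviations from the group means were exchanged, was added only after the first regroupings of the arrays had been seen. Overlaps between comparisons that share arrays were set beside independent expectations and, for IFN-γ against dexamethasone in its presence, beside a simulation without a dexamethasone effect. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6.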

Results

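RNA of bronchial epithelial cells in primary culture was measured on 36 arrays, for 5503 genes. Cells received control medium, dexamethasone, IFN-γ or both, with 4 arrays per treatment at 8 h and 5 at 24 h. The number of arrays limits the precision of each difference. Differences below are log2 values with the standard error of the limma fit, and a gene is said to rise or fall only at an adjusted p under 0.05.

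Control probe sets separated the arrays by time and, at 24 h, into 2 sets. The signal of the Cre spike ran from 1979 to 5666 on the 8 h arrays and from 6056 to 40759 on the 24 h arrays, with no overlap. In 4 of 4 groups at 24 h the arrays of replicates 4 and 5 had more Cre signal than those of replicates 6 to 8, so 24 h counts are also given with this array set as a block and within each set (8 and 12 arrays), as are medians of many lists within each set. The log2 ratio of 3' to 5' ACTB signal was 1.09 on the control array 1 at 8 h and 1.76 on array 1 of both treatments at 8 h. In exact permutation tests of ACTB and GAPDH ratios against control, the smallest p was 0.0317, or 0.38 after adjustment.

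**Figure D1:**
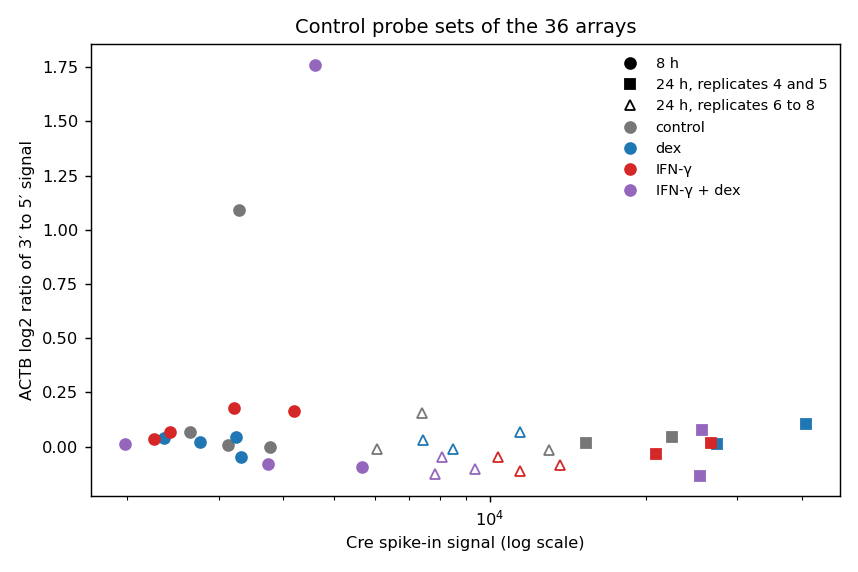
Cre spike signal and ACTB 3' to 5' ratios of the 36 arrays. The 8 h arrays lay between 1979 and 5666 and the 24 h arrays between 6056 and 40759 in Cre signal.

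The first comparison asked how IFN-γ changed gene expression within 8 h (4 arrays against 4). The CXCR3 ligands CXCL10, CXCL9 and CXCL11, which attract T cells and lay at or near the floor in controls, rose by 5.90 ± 0.17, 5.87 ± 0.10 and 5.84 ± 0.13 (adjusted p = 2.2e-24, 3.4e-31 and 1.1e-27). The adhesion molecule ICAM1 rose by 4.78 ± 0.17, the transcription factor IRF1 by 4.41 ± 0.16 and SECTM1 by 4.51 ± 0.21. IDO1, which breaks down tryptophan, rose by 4.10 ± 0.16 and WARS1, which loads tryptophan onto its tRNA, by 3.90 ± 0.17. The largest falls were smaller, with FAM171A1 at -1.56 ± 0.16, SOX4 at -1.52 ± 0.16, THBS2 at -1.32 ± 0.14, DST at -1.25 ± 0.15 and the WNT inhibitor DKK1 at -1.48 ± 0.15. In total 433 genes changed, 220 higher and 213 lower, and 122 of them at least 2-fold, 106 higher and 16 lower. Without control array 1 the counts were 206 higher and 133 lower, and without both arrays of high ACTB ratio 214 and 140. With array weights 1077 genes changed.

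Antigen presentation and antiviral genes rose together at 8 h. Of 14 class I genes 10 rose (10 adjusted over the list alone), with a list median of 1.21 and an adjusted p of 2.0e-19 by camera. The peptide transporter TAP1 rose by 3.43 ± 0.15 and the immunoproteasome subunits PSMB9 and PSMB8 by 2.92 ± 0.12 and 2.23 ± 0.19. Of 12 class II genes 8 rose (9 over the list alone), with a median of 0.63 and adjusted p = 6.7e-14. CD74, the class II invariant chain, rose by 2.23 ± 0.15 and HLA-DMA by 1.05 ± 0.14. HLA-DRA rose by 1.83 ± 0.22, from a mean signal of 36 to 211, a rise that was not called with an offset of 1 (adjusted p = 0.12). Of 31 antiviral genes 29 rose (31 over the list alone), with a median of 1.75 and adjusted p = 1.7e-90. Among them IFIT3 rose by 5.45 ± 0.16, MX1 by 3.76 ± 0.13 and ISG15 by 2.75 ± 0.17. Of the 5 GTPases 4 rose (4 over the list alone; median 2.25, adjusted p = 8.2e-18), with GBP1 up by 3.92 ± 0.14.

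Signalling, death and complement genes also rose at 8 h. In JAK-STAT signalling 8 of 15 genes rose (8 over the list alone; median 0.77, adjusted p = 3.8e-17), among them the feedback inhibitor SOCS1 by 2.63 ± 0.16 and IRF9 by 2.01 ± 0.14. The receptor subunit IFNGR1 stood at 0.10 ± 0.16. Of 18 apoptosis genes 11 rose and 2 fell (12 and 2 over the list alone; median 0.84, adjusted p = 9.6e-12), with APOL1 up by 3.07 ± 0.18, TNFSF10 by 1.67 ± 0.13 and CASP8 by 1.32 ± 0.17. Of 11 complement genes 5 rose (5 higher and 1 lower over the list alone; median 0.18, adjusted p = 3.4e-06), led by SERPING1, an inhibitor of the pathway, at 3.09 ± 0.15. Of 8 lymphocyte chemokines 6 rose (6 over the list alone; median 3.002, adjusted p = 2.9e-28), and CCL2 reached 3.26 ± 0.15. Of 13 tryptophan, nitric oxide and oxidant enzymes 3 rose (3 over the list alone; median 0.13, adjusted p = 0.000382), and they were IDO1, WARS1 and GCH1 (0.83 ± 0.16).

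The inflammatory genes moved both ways at 8 h. Of 20 neutrophil chemokines and NF-κB genes 2 rose and 2 fell (2 and 4 over the list alone). Their median was -0.03 and their mean 0.22, and camera pointed upward without a call (adjusted p = 0.424). CXCL2 rose by 1.41 ± 0.21, while CXCL8 fell by 0.89 ± 0.20, a fall not called with an offset of 100 (adjusted p = 0.084). PTGS2 stood at 0.37 ± 0.18 (adjusted p = 0.268). Of 23 glucocorticoid receptor targets 4 rose and 3 fell (5 and 3 over the list alone; median 0.21). CEBPD rose by 1.23 ± 0.15 and ZFP36 by 1.06 ± 0.17. The list was called at adjusted p = 0.0373, against an adjusted p = 0.257 with an estimated correlation, and was not called without control array 2 (0.0562), control array 3 (0.0602) or IFN-γ array 4 (0.0764). Of 24 matrix genes 3 rose and 4 fell (3 and 5 over the list alone; median -0.12, adjusted p = 0.378), with CCN2 at -0.87 ± 0.18 and THBS1 at -0.70 ± 0.15. Of 31 cell cycle genes 2 fell (3 over the list alone; median -0.21, adjusted p = 0.00404), among them MCM6 at -0.68 ± 0.16. The cell cycle call gave an adjusted p = 0.247 with an estimated correlation and 0.0515 when the dimmest 60% were left out, and the list stood near the floor at 8 h, at 5.89 ± 0.02 (SD) in controls.

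**Figure D2:**
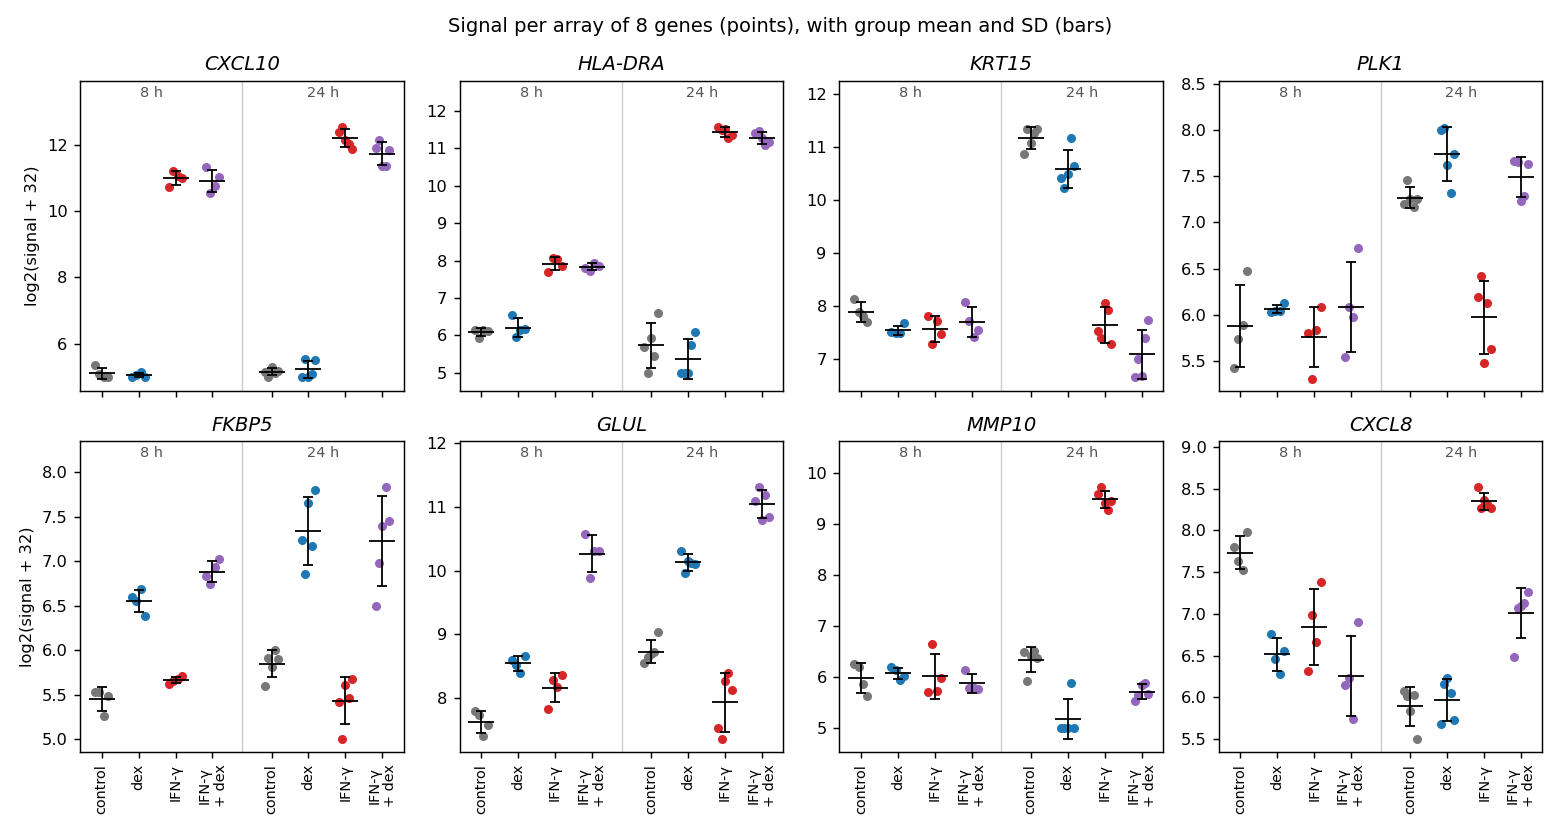
Signals of 8 genes in the 8 groups. CXCL10 rose by 5.90 ± 0.17 at 8 h and 7.05 ± 0.15 at 24 h with IFN-γ, and GLUL by 3.11 ± 0.16 with dexamethasone added to IFN-γ at 24 h.

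At 24 h (5 arrays against 5) IFN-γ again raised the CXCR3 ligands. Their controls lay at or near the floor, so the size and order of their differences follow the offset. CXCL9, CXCL10 and CXCL11 stood at 7.12 ± 0.09, 7.05 ± 0.15 and 6.74 ± 0.12 above control, and the mean signal of CXCL10 went from 2.94 to 4752 ± 903 (SD). The cytokine IL32 rose by 5.81 ± 0.26, HLA-DRA by 5.70 ± 0.20 and WARS1 by 5.46 ± 0.15 (adjusted p = 1.2e-19, 1.3e-22 and 2.4e-25). The basal keratin KRT15 was the gene with the largest fall, at -3.54 ± 0.18 (adjusted p = 1.3e-17), from a mean signal of 2300 ± 316 to 171 ± 48.1. Its log2 signals were 7.28 to 8.054 with IFN-γ at 24 h, against 7.686 to 8.133 in the 8 h controls. The fall is thus one against controls of 24 h. The aldehyde dehydrogenases ALDH3A1 and ALDH3A2 fell, to -3.25 ± 0.26 and -2.08 ± 0.11 against control, and so did GCLC, which makes glutathione, to -2.04 ± 0.12. In total 2294 genes changed, 672 higher and 1622 lower, and 437 at least 2-fold, 223 higher and 214 lower. The balance depended on scaling, with 29.3% of called genes higher, but 35.9% after quantile normalization. The median over all genes was -0.131, and -0.076 after that normalization. With the array set as a block 2527 changed (740 higher, 1787 lower), within replicates 4 and 5 there were 1021 (383 and 638), and within replicates 6 to 8 there were 1911 (570 and 1341). The correlation of the differences between sets was 0.889 across genes.

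Antigen presentation reached further at 24 h than at 8 h. Of 12 class II genes 11 rose (11 over the list alone; median 2.50, adjusted p = 1.8e-19), with HLA-DPA1 up by 5.07 ± 0.14, CD74 by 4.50 ± 0.14 and HLA-DMA by 3.88 ± 0.12. Of 14 class I genes 12 rose and 1 fell (12 and 1 over the list alone; median 2.02, adjusted p = 6.7e-16), with TAP1 up by 3.59 ± 0.13, PSMB9 by 3.08 ± 0.10, PSMB10 by 2.96 ± 0.10 and HLA-F by 2.82 ± 0.19. All 31 antiviral genes tested rose (31 over the list alone; median 2.32, adjusted p = 1.5e-43), with MX1 at 4.73 ± 0.12, IFI27 at 4.39 ± 0.22 and ISG15 at 4.15 ± 0.16. The GTPases rose in 4 of 5 genes (4 over the list alone; median 3.18, adjusted p = 1.8e-08), lymphocyte chemokines in 7 of 8 (7; median 3.74, adjusted p = 6.7e-16) and JAK-STAT signalling in 10 of 15 (10; median 0.56, adjusted p = 5.7e-09). SOCS1 rose by 2.76 ± 0.14 and IRF7 by 1.89 ± 0.14, and IFNGR1 stood at -0.03 ± 0.14. Within replicates 4 and 5 and within 6 to 8 the class II medians were 2.57 and 2.45.

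Inflammatory and complement genes were higher with IFN-γ at 24 h. Of 20 neutrophil chemokines and NF-κB genes 15 rose (15 over the list alone; median 1.40, adjusted p = 1.3e-15; within-set medians 1.29 and 1.35). ICAM1 rose by 5.72 ± 0.15, PTGS2 by 2.64 ± 0.16, CXCL2 by 2.62 ± 0.19 and CXCL8 by 2.45 ± 0.18. Members that restrain NF-κB rose as well, TNFAIP3 by 2.73 ± 0.12 and NFKBIA by 1.75 ± 0.14. Complement rose in 6 of 11 genes (6 higher and 1 lower over the list alone; median 0.32, adjusted p = 3.0e-08), with SERPING1 at 5.18 ± 0.14, C1R at 3.81 ± 0.15, C1S at 3.65 ± 0.14 and CLU at 3.38 ± 0.14. Of 18 apoptosis genes 11 rose and 1 fell (13 and 2 over the list alone; median 0.87, adjusted p = 2.8e-08), among them APOL1 at 3.75 ± 0.16 and PMAIP1 at 1.79 ± 0.18. Of 23 glucocorticoid receptor targets 12 rose and 3 fell (13 and 3 over the list alone; median 0.54, adjusted p = 2.1e-06), with the decoy receptor IL1R2 up by 2.92 ± 0.13 and DUSP1 by 1.71 ± 0.23.

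Of the 31 cell cycle genes 30 fell at 24 h (31 over the list alone; median -0.95, adjusted p = 3.8e-12; within-set medians -1.01 and -0.91). The replication factors MCM6, PCNA and MCM2 stood at -1.91 ± 0.14, -1.84 ± 0.11 and -1.57 ± 0.18, and the mitotic cyclin CCNB2 at -1.78 ± 0.21. Of 10 metallothioneins 6 fell and 1 rose (6 and 1 over the list alone; median -0.43; within-set medians -0.68 and -0.28), with MT1X at -2.14 ± 0.14 and MT1E at -0.84 ± 0.12. Camera did not call the metallothioneins (adjusted p = 0.103), but did after quantile normalization (0.00716) and without a filter (0.047). Of 24 matrix genes 12 rose and 7 fell (12 and 8 over the list alone; median 0.41, adjusted p = 0.00719), with MMP10 up by 3.14 ± 0.17, the urokinase receptor PLAUR by 2.67 ± 0.20 and MMP1 by 2.05 ± 0.16. The matrix call gave an adjusted p = 0.0832 with an estimated correlation and 0.0668 when the dimmest 60% were left out. Of 15 cholesterol synthesis genes 8 rose (8 over the list alone; median 0.42, adjusted p = 0.000802), such as ACAT2 at 0.70 ± 0.13 and MSMO1 at 0.63 ± 0.09.

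The remaining lists changed in single genes at 24 h. Of 17 heat shock and immediate early genes 6 rose and 2 fell (6 and 2 over the list alone; median 0.02, adjusted p = 0.0196), with ATF3 at 1.88 ± 0.13 and IER2 at 0.94 ± 0.12. That call gave an adjusted p = 0.0832 with an estimated correlation and 0.0668 with the dimmest 60% left out. Of 13 tryptophan, nitric oxide and oxidant enzymes 4 rose and 5 fell (4 and 5 over the list alone; median 0.10, adjusted p = 0.103), with IDO1 at 5.45 ± 0.14 and GCH1 at 1.96 ± 0.14 but NQO1 at -1.86 ± 0.15. Of 24 squamous genes 5 rose and 6 fell (5 and 6 over the list alone; median 0.01, adjusted p = 0.357). The crosslinking enzyme TGM1 rose by 2.13 ± 0.20 and S100A9 by 1.21 ± 0.21, while CRABP2 fell by 1.37 ± 0.18 and KRT13 fell by 1.12 ± 0.20. Of 13 secretory markers 5 rose and 2 fell (6 and 2 over the list alone; median 0.06, adjusted p = 0.0753). CEACAM5 rose by 1.44 ± 0.20 and AGR2 fell by 1.51 ± 0.18. MUC1 rose by 2.26 ± 0.27 but was not called with an offset of 1 (adjusted p = 0.145). Of 11 basal markers 3 fell (3 over the list alone; median -0.12, adjusted p = 0.309, but 0.0236 after quantile normalization), which were KRT15, DST (-1.95 ± 0.13) and CAV1 (-0.75 ± 0.12). Of 16 eicosanoid genes 3 rose and 1 fell (2 and 1 over the list alone; median 0.06, adjusted p = 0.103, but 0.0452 with an offset of 100), with CBR1 at -1.004 ± 0.25, not called with an offset of 1 (adjusted p = 0.117).

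Lists of other cell types and of housekeeping genes moved little at 24 h. Of 9 fibroblast markers 1 rose and 2 fell (1 and 2 over the list alone), with a median of 0.12, a mean of -0.03 and an upward camera result at adjusted p = 0.776. The matrix protein SPARC fell by 1.47 ± 0.10 and ACTA2 fell by 0.82 ± 0.16, and PDGFRA rose by 0.97 ± 0.17, though not with an offset of 100 (adjusted p = 0.0785). Of 6 leukocyte markers 1 rose (1 over the list alone; median 0.17, adjusted p = 0.18), which was CD68 at 0.51 ± 0.16. Of 9 ion and water transport genes 1 rose and 1 fell (1 and 1 over the list alone). Their median was -0.14 and their mean -0.10, and camera pointed upward (adjusted p = 0.913). Of 25 ribosomal protein genes 4 fell (3 over the list alone; median -0.11, adjusted p = 0.426, but 0.00797 after quantile normalization), the largest fall being RPL22 at -0.57 ± 0.11. Of the ciliated and endothelial markers 3 and 2 were tested, too few for a test that asked for 5.

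**Figure D3:**
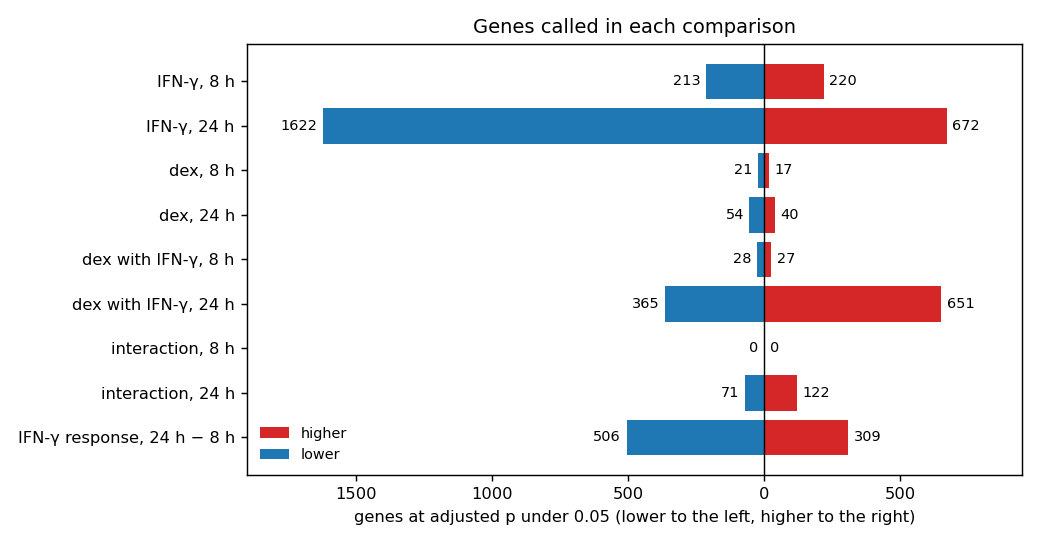
Genes called higher and lower in each comparison. IFN-γ changed 433 genes at 8 h and 2294 at 24 h, and dexamethasone changed 38 and 94.

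The IFN-γ responses at both times were then compared (9 arrays per treatment). IL32 differed most, with a response larger at 24 h by 4.83 ± 0.38 (adjusted p = 1.5e-11). Class II genes followed, with HLA-DPA1 larger by 4.02 ± 0.21, HLA-DRA by 3.87 ± 0.30 and HLA-DMA by 2.84 ± 0.18. The chemokines CCL5 and CXCL8 were larger by 3.54 ± 0.22 and 3.35 ± 0.27, and TGM2 by 3.65 ± 0.28. Differences below 0 were largest for ALDH3A1 (-3.59 ± 0.39), KRT15 (-3.23 ± 0.27), RGS9 (-2.66 ± 0.52), OLFML2A (-2.28 ± 0.26) and MT1X (-1.85 ± 0.20). The chemokine CX3CL1 stood at -1.78 ± 0.21. In total 815 genes differed, 309 higher and 506 lower, 248 of them at least 2-fold (140 and 108), 1079 with the 24 h array set as a block (379 and 700) and 1519 with array weights. Of the called genes 37.9% were higher, but 45.6% after quantile normalization. The array set of the 24 h arrays cannot be told apart from time. The difference was not called for IRF1 (-0.11 ± 0.22), TAP1 (0.16 ± 0.19) and PSMB9 (0.17 ± 0.16; adjusted p = 0.812, 0.668 and 0.545).

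By list, class II genes were higher in 8 of 12 (9 over the list alone; median 2.03, adjusted p = 3.2e-20) and neutrophil chemokines and NF-κB genes in 12 of 20 (13; median 1.20, adjusted p = 1.1e-20) in the later response. IL1B was larger by 2.32 ± 0.19, TNFAIP3 by 2.80 ± 0.19 and PTGS2 by 2.27 ± 0.23. Complement was higher in 5 of 11 (5; median 0.21, adjusted p = 5.2e-09), class I in 6 of 14 (6; median 0.53, adjusted p = 3.4e-06) and cholesterol synthesis in 7 of 15 (8; median 0.70, adjusted p = 1.8e-06). Antiviral genes were higher in 13 and lower in 6 of 31 (15 and 7 over the list alone; median 0.40, adjusted p = 1.7e-05), with RSAD2 larger by 2.27 ± 0.17 and IFI27 by 2.57 ± 0.33. Lymphocyte chemokines (4 higher and 1 lower; 5 and 1 over the list alone; median 0.73, adjusted p = 3.8e-05) and GTPases (3 higher; 3; median 0.64, adjusted p = 0.00727) were not called with an offset of 1 (0.0873 and 0.0832). Matrix genes (10 higher and 3 lower; 14 and 5; median 0.53, adjusted p = 2.6e-05) and glucocorticoid receptor targets (9 and 4; 9 and 5; median 0.435, adjusted p = 7.7e-05) had larger responses at 24 h as lists, with members differing both ways. Cell cycle genes were lower in 18 of 31 (27 over the list alone; median -0.74, adjusted p = 1.7e-11), with PCNA at -1.63 ± 0.17, but stood near the floor at 8 h. Secretory markers (5 higher and 1 lower; median 0.20, adjusted p = 0.0248) gave an adjusted p = 0.0693 with an estimated correlation, and 0.101 with the dimmest 60% left out. Heat shock genes (3 higher and 1 lower; median 0.22, adjusted p = 0.00636) gave 0.0634 with the dimmest 60% left out.

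Dexamethasone alone was compared with control to see the glucocorticoid response of these cells. At 8 h (4 arrays against 4) the signalling regulator RGS2 rose by 1.66 ± 0.14 (adjusted p = 2.6e-09), FSTL3 by 1.42 ± 0.21, the receptor chaperone FKBP5 by 1.10 ± 0.19, glutamine synthetase GLUL by 0.91 ± 0.17 and FOS by 0.80 ± 0.13. The phosphatase DUSP1 rose by 1.82 ± 0.26 and the WNT inhibitor SFRP1 by 1.05 ± 0.14, neither called with an offset of 1 (adjusted p = 0.0632 and 0.187). The urokinase PLAU fell by 0.90 ± 0.12 (adjusted p = 2.5e-05), FLRT2 fell by 0.73 ± 0.13 and the death ligand TNFSF10 fell by 0.73 ± 0.13. CXCL8 fell by 1.22 ± 0.20, from a mean signal of 182 to 60.1, though not with an offset of 100 (adjusted p = 0.221). TSC22D3 stood at 0.49 ± 0.24, PTGS2 at -0.46 ± 0.17, IRF1 at -0.44 ± 0.16 and NFKBIA at 0.11 ± 0.15 without a call.

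In total 38 genes changed with dexamethasone at 8 h, 17 higher and 21 lower (44.7% higher), and 10 at least 2-fold. After quantile normalization 18 were higher and 14 lower (56.2% higher). The count fell to 16, 17, 18 and 22 without control arrays 1, 2, 3 and 4, and to 18, 16, 21 and 21 without dexamethasone arrays 1, 2, 3 and 4. It was 17 with an offset of 1, 18 without both arrays of high ACTB ratio, 64 with the 24 h array set as a block, 84 in a fit of the 8 h arrays alone and 520 with array weights. Of 23 glucocorticoid receptor targets 6 rose (8 over the list alone; median 0.22, adjusted p = 3.0e-10). Metallothioneins, with 0 genes called (1 higher over the list alone; median 0.33, MT1E at 0.46 ± 0.14), were called as a list at adjusted p = 0.000531, but gave an adjusted p = 0.371 with an estimated correlation. Cholesterol synthesis had 0 genes called either way (median 0.09, adjusted p = 0.0293) and gave an adjusted p = 0.365 with an estimated correlation. Its call was also lost after quantile normalization (0.105), with the dimmest 60% left out (0.07) and without control array 3 (0.172), control array 4 (0.0899) or dexamethasone array 4 (0.113).

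At 24 h (5 arrays against 5) dexamethasone raised RGS2 by 1.98 ± 0.13 (adjusted p = 7.5e-13), the acute phase protein SAA1 by 1.72 ± 0.14, FKBP5 by 1.499 ± 0.17 and GLUL by 1.40 ± 0.16. SFRP1 rose by 1.13 ± 0.13, the sodium channel subunit SCNN1A by 1.05 ± 0.21 and FSTL3 by 0.90 ± 0.19. The collagenase MMP1 and the stromelysin MMP10 fell, at -1.13 ± 0.17 and -1.16 ± 0.17, and so did NUPR1 (-1.18 ± 0.23), the water channel AQP3 (-0.99 ± 0.14) and ASS1, which makes arginine (-0.95 ± 0.18). TNFSF10 fell by 0.74 ± 0.12 and IER3 fell by 0.54 ± 0.11. IRF1 fell by 0.95 ± 0.14, though not with an offset of 100 (adjusted p = 0.0851). CXCL8, lower at 8 h, stood at 0.08 ± 0.18 at 24 h (adjusted p = 0.91), with mean signals of 28.1 in controls and 31.5 with dexamethasone. ICAM1 stood at -0.20 ± 0.15 and TSC22D3 at 0.59 ± 0.22 (adjusted p = 0.647 and 0.194).

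The 24 h count for dexamethasone alone was 94, with 40 higher and 54 lower, 9 of them at least 2-fold. Without dexamethasone array 7 it was 206, without dexamethasone arrays 5 and 6 it was 52 and 48, and without control arrays 6 and 7 it was 60 and 56. With the array set as a block 184 changed (81 higher, 103 lower), within replicates 4 and 5 there were 2 (2 higher) and within 6 to 8 there were 12 (8 and 4). The correlation of differences between sets was 0.269. A fit of the 24 h arrays alone called 32. Of 23 glucocorticoid receptor targets 6 rose (10 higher and 1 lower over the list alone; median 0.18, adjusted p = 1.6e-08). Of 10 metallothioneins 6 rose (6 higher and 1 lower; median 0.64, adjusted p = 6.8e-07), with MT1E at 0.73 ± 0.12 and MT1B at 0.68 ± 0.15. Of 24 matrix genes 1 rose and 6 fell (1 and 10 over the list alone; median -0.29, adjusted p = 2.1e-05). The cell cycle list was higher as a whole, with 1 gene called (5 over the list alone; median 0.29, adjusted p = 6.4e-10), and MCM2 stood at 0.61 ± 0.18 (adjusted p = 0.0691).

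The other lists called with dexamethasone at 24 h had medians below 0. The squamous list, with 1 gene lower (2 over the list alone; median -0.31, adjusted p = 2.1e-05), gave an adjusted p = 0.228 with an estimated correlation. Its called gene CRABP2, which carries retinoic acid, fell by 0.84 ± 0.18. JAK-STAT signalling, where IRF1 was the 1 gene called (1 over the list alone; median -0.20, adjusted p = 0.025), was not called with an offset of 100 (0.109), without a filter (0.0562) or without dexamethasone array 5 (0.0955). Tryptophan, nitric oxide and oxidant enzymes, with 1 gene lower (2 over the list alone; median -0.15, adjusted p = 0.0398), were not called without a filter (0.119), with array weights (0.157) or without control arrays 4, 5 and 8 (0.142, 0.0715 and 0.0706) or dexamethasone arrays 5 and 8 (0.0981 and 0.0809). The called member, the glutathione peroxidase GPX2, fell by 0.51 ± 0.11.

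Dexamethasone added to IFN-γ was compared with IFN-γ alone to see what the glucocorticoid changed in stimulated cells. At 8 h (4 arrays against 4) GLUL rose by 2.10 ± 0.17, RGS2 by 1.91 ± 0.14 and FSTL3 by 1.47 ± 0.21 (adjusted p = 3.6e-10 for GLUL and 5.3e-11 for RGS2). The methyltransferase NNMT rose by 1.32 ± 0.19 and MT1E by 0.73 ± 0.14. DUSP1 rose by 1.85 ± 0.26, FKBP5 by 1.22 ± 0.19, SFRP1 by 1.09 ± 0.14 and GAS1 by 1.05 ± 0.17, none of them called with an offset of 1 (adjusted p = 0.0625, 0.0506, 0.0834 and 0.28). PLAU fell by 1.002 ± 0.12, the AP-1 subunit JUNB fell by 1.06 ± 0.21 and the antiviral RSAD2 fell by 0.64 ± 0.13. Of the IFN-γ-induced genes named above, IDO1 and TNFSF10 also fell, at -0.66 ± 0.16 and -0.51 ± 0.13 (adjusted p = 0.0256 and 0.0434). Neither was called with an offset of 1 (0.219 and 0.0828), nor IDO1 without IFN-γ array 4 (0.0917) or TNFSF10 without IFN-γ array 3 (0.123). Among those not called, CXCL11 stood at 0.06 ± 0.13, GBP1 at -0.13 ± 0.14, ICAM1 at -0.29 ± 0.17 and CCL2 at -0.52 ± 0.15 (adjusted p = 0.896, 0.775, 0.484 and 0.0963).

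The 8 h count for dexamethasone on top of IFN-γ was 55, with 27 higher and 28 lower, 11 of them at least 2-fold. Without IFN-γ arrays 2, 3 and 4 it was 22, 30 and 31, and without arrays 1 and 3 of both treatments it was 33 and 32. It was 32 with an offset of 1, 119 with an offset of 100, 143 with the 24 h array set as a block, 174 in the 8 h arrays alone and 734 with array weights. Of 23 glucocorticoid receptor targets 7 rose (8 higher and 1 lower over the list alone; median 0.26, adjusted p = 5.4e-09). Metallothioneins, with 1 of 10 higher (5 over the list alone; median 0.41, adjusted p = 4.8e-06), gave an adjusted p = 0.173 with an estimated correlation. The squamous list, with 1 of 24 lower (1 higher and 7 lower over the list alone; median -0.24, adjusted p = 0.00137), gave an adjusted p = 0.241 with an estimated correlation. Ribosomal proteins had 0 genes called either way (median 0.24, adjusted p = 3.9e-09) and gave an adjusted p = 0.241 with an estimated correlation and 0.192 after quantile normalization, where the median was 0.05. The cell cycle list had 0 genes called (median 0.10, adjusted p = 0.0231) and gave an adjusted p = 0.241 with an estimated correlation. It was not called with the dimmest 60% left out (0.0617) or without IFN-γ arrays 1 and 3 (0.11 and 0.061) or array 4 of both treatments (0.0848). Antiviral genes, with 2 of 31 lower (3 over the list alone; median -0.13, adjusted p = 0.0374), gave an adjusted p = 0.193 with an estimated correlation. Their call was lost with an offset of 1 (0.402), the dimmest 60% left out (0.0866), array weights (0.0749), without IFN-γ array 2 (0.198) and without arrays 2 and 4 of both treatments (0.136 and 0.0677).

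Dexamethasone added to IFN-γ was also compared with IFN-γ alone at 24 h (5 arrays against 5). GLUL rose by 3.11 ± 0.16 (adjusted p = 1.5e-16), from a mean signal of 222 to 2098 ± 322 (SD). SAA1 rose by 2.59 ± 0.14, RGS2 by 2.21 ± 0.13, FKBP5 by 1.80 ± 0.17, NNMT by 1.58 ± 0.17 and LAS1L by 1.72 ± 0.15. MMP10 fell by 3.77 ± 0.17 (adjusted p = 4.6e-18), from 685 ± 85.3 to 20.6, and LY6D fell by 3.09 ± 0.21. Also lower were MMP1 (-2.24 ± 0.17), AQP3 (-1.96 ± 0.14), the decoy receptor IL1R2 (-1.91 ± 0.13) and the chemokine CCL5 (-1.84 ± 0.14). CLDN4 fell by 2.60 ± 0.49, a gene with mean signals below 0 in the 24 h groups without IFN-γ. The called genes numbered 1016, 651 higher and 365 lower, 109 of them at least 2-fold (68 and 41). The share of called genes that were higher was 64.1%, but 58% after quantile normalization. With the array set as a block there were 1294 (803 and 491), within replicates 4 and 5 there were 162 (100 and 62) and within 6 to 8 there were 669 (435 and 234). The correlation of differences between sets was 0.653.

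Cell cycle genes, lower with IFN-γ, were higher again with both treatments at 24 h. Of 31 genes 27 rose (30 over the list alone; median 0.86, adjusted p = 2.1e-23; within-set medians 0.76 and 0.91). The mitotic kinases PLK1 and AURKA rose by 1.52 ± 0.19 and 1.48 ± 0.21, CDC20 by 1.43 ± 0.16 and KIF2C by 1.54 ± 0.21. The mean signal of PLK1 was 123 in controls, 32.8 with IFN-γ and 150 with both. Of 10 metallothioneins 6 rose (7 over the list alone; median 1.09, adjusted p = 7.0e-07; within-set medians 1.42 and 0.84), with MT1E at 1.47 ± 0.12 and MT1X at 1.22 ± 0.14. MYC rose by 1.22 ± 0.14 and SCNN1A by 1.28 ± 0.21. TSC22D3, a glucocorticoid target, rose by 1.01 ± 0.22, and DUSP1 by 0.93 ± 0.23, though not with an offset of 1 (adjusted p = 0.241). Of 23 glucocorticoid receptor targets 8 rose and 4 fell (8 and 5 over the list alone; median 0.11). That list was not called (adjusted p = 0.0873), but was called after quantile normalization (0.0268), with an offset of 1 (0.0458), with the dimmest 60% left out (0.0189) and without IFN-γ array 4 or 5 (0.0413 and 0.0409).

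Chemokines and inflammatory genes fell with both treatments at 24 h. Of 20 neutrophil chemokines and NF-κB genes 1 rose and 12 fell (1 and 12 over the list alone; median -0.51, adjusted p = 5.8e-08; within-set medians -0.44 and -0.50). Among those that fell were CXCL8 (-1.34 ± 0.18), IL1B (-1.09 ± 0.13), PTGS2 (-0.91 ± 0.16) and the inhibitor NFKBIA (-0.56 ± 0.14), and CCL20 was the 1 member that rose, by 1.33 ± 0.13. Of 8 lymphocyte chemokines 5 fell (5 over the list alone; median -0.46, adjusted p = 7.3e-07; within-set medians -0.44 and -0.51), with CCL2 at -1.43 ± 0.14. CXCL9 fell by 0.46 ± 0.09 and ICAM1 fell by 0.52 ± 0.15, against IFN-γ rises of 7.12 ± 0.09 and 5.72 ± 0.15, and neither was called with an offset of 1 (adjusted p = 0.202 and 0.525). CXCL11, GBP1, IDO1, HLA-DRA, IRF1 and TAP1 were not called, at -0.23 ± 0.12, -0.03 ± 0.12, -0.10 ± 0.14, -0.16 ± 0.20, -0.05 ± 0.14 and 0.14 ± 0.13.

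Of the lists of interferon genes, those of antiviral genes, JAK-STAT signalling and GTPases were called lower with both treatments at 24 h. Class I (1 higher of 14; median -0.075, adjusted p = 0.687) and class II (1 lower of 12; median -0.13, adjusted p = 0.128) were not called, but class II was called lower with an offset of 100 (0.0171) and without a filter (0.0214). Of 31 antiviral genes 8 fell (8 over the list alone; median -0.09, adjusted p = 0.0016), with RSAD2 at -1.12 ± 0.12 and ISG15 at -0.82 ± 0.16. Of 15 genes of JAK-STAT signalling 3 fell (4 over the list alone; median -0.13, adjusted p = 0.014), among them IRF7 at -0.62 ± 0.14 and IFNGR2 at -0.55 ± 0.12. SOCS1 fell by 1.13 ± 0.14, though not with an offset of 1 (adjusted p = 0.0624). Of 5 GTPases 3 fell (3 over the list alone; median -0.46, adjusted p = 0.014). With an offset of 1 the antiviral, JAK-STAT and GTPase lists were not called (0.0574, 0.0574 and 0.224). Tryptophan, nitric oxide and oxidant enzymes were lower in 3 and higher in 1 of 13 (median -0.18, adjusted p = 0.0192), with KYNU at -0.49 ± 0.11, a gene for which another probe set was called in the opposite direction. Apoptosis genes, 1 higher and 2 lower of 18, had a median of 0.01, a mean of -0.02 and a downward camera result at adjusted p = 0.432, with TNFSF10 at -0.84 ± 0.12. Complement, 1 higher and 2 lower of 11, was not called (median -0.05, adjusted p = 0.333), with CFB at -0.49 ± 0.11.

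Protease, lipid and differentiation genes also fell with both treatments at 24 h. Of 24 matrix genes 3 rose and 14 fell (4 and 15 over the list alone; median -0.42, adjusted p = 4.9e-08; within-set medians -0.53 and -0.45), with HBEGF at -1.61 ± 0.21 and MMP9 at -1.42 ± 0.17. Of 15 cholesterol synthesis genes 9 fell (11 over the list alone; median -0.52, adjusted p = 4.9e-08; within-set medians -0.33 and -0.55), with MSMO1 at -0.66 ± 0.09 and FDPS at -0.57 ± 0.09. Of 24 squamous genes 1 rose and 9 fell (1 and 14 over the list alone; median -0.44, adjusted p = 9.3e-08; within-set medians -0.51 and -0.46), and the list gave an adjusted p = 0.0644 with an estimated correlation. KLK10 fell by 1.78 ± 0.19 and the cornified envelope precursors SPRR1A and SPRR1B stood at -1.35 ± 0.22 and -1.33 ± 0.20. Of 13 secretory markers 4 fell (4 over the list alone; median -0.20, adjusted p = 0.00465), with ALDH1A3 at -1.41 ± 0.13 and CEACAM5 at -1.04 ± 0.20. Basal markers, 2 of 11 lower (median -0.26, adjusted p = 0.0368), gave an adjusted p = 0.225 with an estimated correlation and 0.156 after quantile normalization, and were not called without IFN-γ array 5 (0.0564) or arrays 6 and 7 of both treatments (0.0843 and 0.0727). Leukocyte markers, 2 of 6 lower (median -0.17, adjusted p = 0.0251), gave an adjusted p = 0.121 with an estimated correlation, 0.0643 without a filter and 0.0611 without array 7 of both treatments, with CD68 at -1.06 ± 0.16. Heat shock genes, 3 higher and 4 lower of 17, had a median of 0.16 and a mean of 0.07 against a downward camera result at adjusted p = 0.945. Ribosomal proteins (median 0.11, adjusted p = 0.0873) were called after quantile normalization (0.0194), with an offset of 100 (0.047) and without a filter (0.0258).

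The interaction asked whether the dexamethasone effect differed with IFN-γ present. At 8 h limma called 0 genes (16 arrays). An unadjusted p under 0.05 was found for 287, close to what chance alone would give among 5503 genes. The nearest was GLUL, with an effect larger by 1.19 ± 0.25 (adjusted p = 0.0609), which was called after quantile normalization (0.0253), with an offset of 100 (0.00806) and without array 2 of both treatments (0.0439). RSAD2 stood at -0.64 ± 0.18, IDO1 at -0.72 ± 0.22, HSPA1B at 1.01 ± 0.29 and CXCL8 at 0.64 ± 0.28. Quantile normalization called 3 genes, 2 higher and 1 lower, an offset of 100 called 4, a floor of 20 called 5, the trended prior 3, the 24 h array set as a block 3, the 8 h arrays alone 4 and array weights 52. Without control array 4, array 4 of both treatments or array 2 of both treatments the counts were 2, 2 and 1. Squamous genes had 0 called (median -0.30, adjusted p = 0.00116) and gave an adjusted p = 0.527 with an estimated correlation and 0.0973 without dexamethasone array 1. Ribosomal proteins had 0 called (median 0.18, adjusted p = 0.00145) and gave an adjusted p = 0.663 with an estimated correlation. That call was lost after quantile normalization (0.553), with array weights (0.0536), without both arrays of high ACTB ratio (0.34) and without IFN-γ array 1 (0.129) or arrays 1 and 4 of both treatments (0.162 and 0.146).

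At 24 h (20 arrays) the effect of dexamethasone differed with IFN-γ for 193 genes, 122 higher and 71 lower, 47 of them at least 2-fold. The split was 122 and 35 with an offset of 1, and 105 and 89 with an offset of 100. It was larger by 1.71 ± 0.22 for GLUL (adjusted p = 6.9e-06), by 1.41 ± 0.29 for KIF2C, by 1.32 ± 0.24 for NNMT, by 1.31 ± 0.30 for AURKA and by 0.74 ± 0.18 for MT1E. The difference was negative for LY6D (-2.20 ± 0.30), DDAH2 (-1.83 ± 0.38), IL1R2 (-1.80 ± 0.18), CCL5 (-1.75 ± 0.20), CCL2 (-1.53 ± 0.20) and CXCL8 (-1.42 ± 0.25). It was also negative for RSAD2, ALDH1A3 and AQP3, at -1.12 ± 0.16, -1.26 ± 0.18 and -0.97 ± 0.20. The 24 h log2 signals of CXCL8 without IFN-γ lay near the floor, at 5.502 to 6.078 in controls and 5.68 to 6.23 with dexamethasone. At 8 h they stood higher in controls, at 7.525 to 7.975, and at 6.283 to 6.756 with dexamethasone alone. The negative difference of CXCL8 at 24 h may thus follow its low start. Room to fall without IFN-γ was not tested for the other genes. MMP10 stood at -2.61 ± 0.23 (adjusted p = 5.5e-09) but was not called with an offset of 1 (0.868). Most MMP10 values with dexamethasone alone at 24 h lay at or near the floor of 5, so the size of this difference follows the floor. UCN was higher by 1.90 ± 0.47, not called with an offset of 1 (adjusted p = 0.328), and CLDN4 stood at -2.60 ± 0.69, not called with an offset of 1 (0.329), without a filter (0.0506) or without array 4 of both treatments (0.0562). IRF1, higher by 0.90 ± 0.21, was not called with an offset of 100 (adjusted p = 0.338). SOCS1, at -0.85 ± 0.20, turned to 0.65 without a call with an offset of 1.

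With the array set as a block 331 genes had an interaction at 24 h (221 higher, 110 lower), within replicates 4 and 5 there were 0 and within 6 to 8 there were 41 (24 and 17). The correlation between sets was 0.323. A fit of the 24 h arrays alone called 83. Cell cycle genes were higher in 10 of 31 (23 over the list alone; median 0.60, adjusted p = 8.8e-14). Cholesterol synthesis was lower in 2 of 15 (9 over the list alone; median -0.46, adjusted p = 9.5e-10), with MSMO1 at -0.65 ± 0.13. Lymphocyte chemokines were lower in 3 of 8 (4 over the list alone; median -0.51, adjusted p = 5.8e-09), neutrophil chemokines and NF-κB genes lower in 4 and higher in 1 of 20 (7 and 1 over the list alone; median -0.34, adjusted p = 2.7e-06) and matrix genes lower in 4 and higher in 1 of 24 (6 and 1; median -0.23, adjusted p = 0.000212). Of the chemokines that attract lymphocytes, CXCL9 and CXCL10 lay at or near the floor of 5 without IFN-γ at 24 h. CXCL9 reached at most 5.04 in controls and 5.12 with dexamethasone, and CXCL10 at most 5.301 and 5.53. Dexamethasone alone could thus hardly lower them, and a negative difference for them may follow the floor. Room to fall was not tested for the other members of these lists. Metallothioneins (1 higher, 3 over the list alone; median 0.46, adjusted p = 0.00497) gave an adjusted p = 0.277 with an estimated correlation. Squamous genes (1 higher and 1 lower, 1 and 5 over the list alone; median -0.17, adjusted p = 0.00272) gave an adjusted p = 0.401 with an estimated correlation. GTPases (0 called, 2 lower over the list alone; median -0.38, adjusted p = 0.023) were not called with an offset of 1 (0.563). Antiviral genes (2 lower, 3 over the list alone; median -0.08, adjusted p = 0.0155) gave an adjusted p = 0.0963 with an estimated correlation, 0.058 after quantile normalization, 0.438 with an offset of 1 and 0.222 with the dimmest 60% left out. Within replicates 4 and 5 and within 6 to 8 the medians were 0.67 and 0.63 for cell cycle, -0.40 and -0.48 for cholesterol synthesis, and -0.51 and -0.56 for lymphocyte chemokines. They were further apart for neutrophil chemokines and NF-κB genes (-0.48 and -0.28), matrix genes (-0.43 and -0.12), metallothioneins (0.70 and 0.255), squamous genes (-0.37 and -0.26) and GTPases (-0.52 and -0.07), and stood at -0.07 and -0.04 for antiviral genes. Glucocorticoid receptor targets had a median of 0.04 and a mean of -0.03, and ion transport genes 0.08 and -0.08, both with a downward camera result that was not called (0.257 and 0.284).

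**Figure D4:**
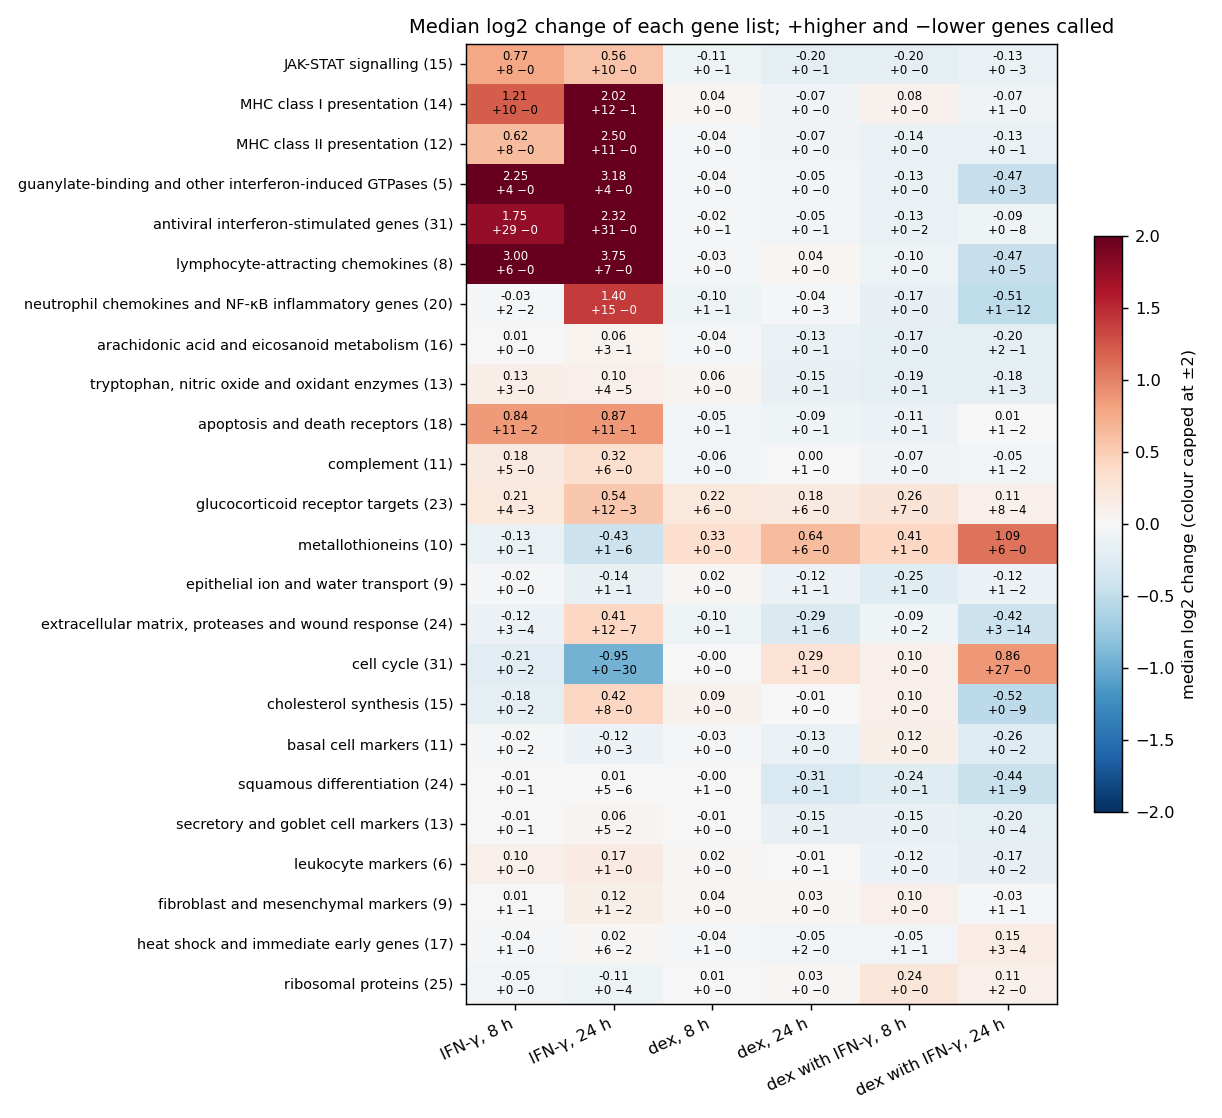
Median change of each gene list with IFN-γ, with dexamethasone and with dexamethasone added to IFN-γ, at 8 h and 24 h. At 24 h the cell cycle list stood at -0.95 with IFN-γ and 0.86 with dexamethasone added to IFN-γ.

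IFN-γ-induced genes as a class were slightly lower with dexamethasone. Over 223 genes raised by IFN-γ at 24 h, the median difference between both treatments and IFN-γ at 8 h was -0.124 (camera p = 0.000607, 0.00372 with an estimated correlation). Of these genes 156 lay below 0, and 10 were called lower and 5 higher. Over 106 genes raised at 8 h, the median at 24 h was -0.161 (camera p = 3.1e-06, 2.9e-05 with an estimated correlation), with 72 below 0, 24 called lower and 3 higher. The medians of single arrays of both treatments against the mean of IFN-γ lay between -0.152 and -0.062 at 8 h and between -0.18 and -0.079 at 24 h. With genes chosen at the same time from splits of the replicate numbers the 24 h median was -0.293, and with genes chosen in the same arrays -0.306, against -0.015 simulated without a dexamethasone effect. At 8 h the same-array value was -0.174, against -0.024 simulated.

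The comparisons shared genes as follows. IFN-γ raised 192 genes and lowered 152 at both times, against 26.9 and 62.8 for independent calls, and 2 and 15 went opposite ways. Dexamethasone alone raised 8 and lowered 5 at both times (0.1 and 0.2 for independent calls), among them RGS2, FKBP5, GLUL and TNFSF10. Dexamethasone with and without IFN-γ shared 7 higher and 3 lower genes at 8 h (0.1 and 0.1) and 35 and 37 at 24 h (4.7 and 3.6), with correlations of 0.254 and 0.436 across genes. At 24 h 505 genes lowered by IFN-γ were raised by added dexamethasone, against 191.9 for independent calls. Another 197 genes raised by IFN-γ were lowered (44.6 for independent calls). The simulation without a dexamethasone effect gave 0 for the first count, which it had to, since no gene changed in its second comparison. Neither reference measures what the shared IFN-γ arrays add to these overlaps. Because the IFN-γ arrays enter both comparisons, the correlation of -0.454 across genes at 24 h was set beside -0.12 simulated and -0.36 from splits of the replicate numbers. At 8 h it was -0.263, against -0.205 simulated and -0.042 from these splits.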

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

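Tests of TFRC, of a source shared by number 1 and of the array set were chosen only after the results had been seen. So were those of scaling and of the low start of cell cycle genes. The others were recorded as written before. Those of a wrong label and of a few low arrays still concern patterns already seen in these data.

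A rule for single values that stand apart (Dixon's ratio within a group) picked 18 of 216 groups of values, or 8.3%, where about 1 in 20 would be picked by chance. In 4 of them every other array of the group lay at the floor of 5, which were CXCL9 at 5.04 in control array 8 and 5.12 in dexamethasone array 4 at 24 h, and SOCS1 at 5.09 in dexamethasone array 6 at 24 h and 5.07 in array 1 at 8 h. At 24 h, control array 4 had WARS1 at 7.85 and NR3C1 at 6.47, control array 5 had IFNGR2 at 8.96, IFN-γ array 4 had NFKBIA at 10.21 and NR3C1 at 7.37, and IFN-γ array 8 had JAK2 at 5.97. With both treatments at 24 h, array 7 had IRF1 at 9.55 and NFKBIA at 9.58, and array 4 had CXCL8 at 6.48. At 8 h, control array 4 had MT2A at 9.37, IFN-γ array 1 had CXCL11 at 10.75 and IFN-γ array 4 had SGK1 at 6.90.

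The log2 ratio of 3' to 5' ACTB signal was picked in 2 arrays at 8 h, at 1.09 for array 1 of the controls and 1.76 for array 1 of both treatments. A target short of 5' sequence may lie behind it, since the lower TFRC ratio of both arrays was 1.878, above the 0.954 to 1.664 of the 14 others. A wrong IFN-γ label was excluded, because 0 of these arrays had antiviral genes nearer to the other state. A source shared by number 1 stays open, since the arrays of that number went both ways. The higher correlation with its IFN-γ array was -0.157, but its dexamethasone array stood at 0.082 with the control array and 0.134 with the array of both treatments. Whether RNA or labelling was at fault stays open.

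The IFN-γ response differed between times for 815 genes. It was larger at 24 h by 4.83 for IL32, 4.02 for HLA-DPA1, 3.87 for HLA-DRA, 3.65 for TGM2 and 3.54 for CCL5, and stood at -3.59 for ALDH3A1, -3.23 for KRT15, -2.66 for RGS9, -2.28 for OLFML2A and -1.85 for MT1X. Random regroupings of time gave at most 87 genes, and 1 of 100, the real one, gave as many, so chance was excluded.

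A compressed range of the 8 h arrays was excluded only as the whole cause of the larger response. Of 91 genes raised on top of dexamethasone at 8 h, 16, or 17.6%, were called with a smaller response at 24 h. That includes falls, as for GCLM (-0.63 ± 0.18 with IFN-γ at 24 h). Another 34, or 37.4%, were called with a larger response, and the median difference was 0.306. Compression thus stays open for the genes with a larger response. The array set could not be excluded, since 0 of the 8 h arrays lay inside the Cre range of the 24 h arrays. A low start at 8 h may explain part of the lower responses. It held for 11.3% of all genes with a lower response, a share between the bounds of 10 and 50 set in advance, and for 55.6% of the cell cycle genes among them, 10 of 18. Whether time or array set made the rest of the difference stays open.

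The dexamethasone effect differed with IFN-γ at 24 h for 193 genes, with UCN at 1.90, GLUL at 1.71, KIF2C at 1.41, NNMT at 1.32, AURKA at 1.31, MMP10 at -2.61, CLDN4 at -2.60, LY6D at -2.20, DDAH2 at -1.83 and IL1R2 at -1.80. Of these genes, UCN, MMP10 and CLDN4 were not called with an offset of 1. Most MMP10 values with dexamethasone alone lay at or near the floor. Room to fall without IFN-γ was not tested for the others with a negative difference. In 3 of 100 regroupings as many genes were called as the 193. The highest gave 467 and exchanged IFN-γ and both treatments as whole groups, so it carried the dexamethasone effect itself. At 8 h limma called 0 genes, with 287 at an unadjusted p under 0.05, close to what chance alone would give. With 0 genes called, 100 of 100 regroupings had to give as many (highest 22), and that count of regroupings says nothing about chance.

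Cell cycle genes were lower with IFN-γ and higher again with dexamethasone at 24 h. A few low arrays were excluded as the cause, since all 5 IFN-γ arrays had list medians below every array of both treatments. Scaling was excluded, with a median rise of 0.833 after quantile normalization, and so was the array set, with 0.758 as the lower of the within-set medians. The tables hold no count of cells or of divisions, so whether growth itself changed stays open.

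For the other counts, the real grouping was set beside splits of the same arrays. At 8 h 1 of 35 splits, the real one, gave as many genes for IFN-γ (433, highest other 1), for dexamethasone (38, highest other 1) and for dexamethasone on top of IFN-γ (55, highest other 1). At 24 h it was 1 of 100 for IFN-γ (2294, highest other 1363) and 1 of 100 for dexamethasone on top of IFN-γ (1016, highest other 509). For dexamethasone at 24 h it was 4 of 100 (94, highest other 251), and the highest split put arrays 4 and 5 and 1 more against the rest, so it followed the 24 h array set. That points to a structure of the samples, and with the set as a block 184 genes were called, 2 and 12 within the sets. The effect on IFN-γ-induced genes was as far from 0 in 1 of 35 splits at 8 h (-0.124, highest other 0.099) and 1 of 100 at 24 h (-0.161, highest other 0.11).

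For the 79 list calls, 13 of 100 regroupings of the treatments gave as many, with a median of 59 and a highest of 94, so chance was not excluded by that test. Those regroupings carry the treatment effects along. With deviations from the group means regrouped instead, a reference added after the first had been seen, 0 of 99 gave as many (median 14, highest 34). With an estimated correlation the median was 0 and the highest 6, against 58.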

How the results depend on the processing

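The floor of 20, the fits without both arrays of high ACTB ratio, and the block and fits by 24 h array set were chosen only after results had been seen. The camera run with an estimated correlation was planned, but its count was made an alternative only at that stage. The other alternatives were fixed before the data were examined. All settings written down beforehand were run. Where a value moved, the cause was not tested.

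The counts of IFN-γ genes held best. They stayed within 1.5 times of 433 at 8 h and 2294 at 24 h in most settings, but array weights, which were higher for 8 h arrays (median 1.42) than for 24 h arrays (0.77), gave 1077 at 8 h and 1519 for the comparison of times. Within replicates 4 and 5 IFN-γ changed 1021 genes at 24 h. Leaving out any 1 array gave 339 to 422 at 8 h, 2066 to 2285 at 24 h and 677 to 820 for the comparison of times. At 8 h the genes lower with IFN-γ went from 213 to 133 without control array 1 and 140 without both arrays of high ACTB ratio, those higher from 220 to 206 and 214. A 2-fold threshold left 122, 437 and 248.

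The dexamethasone counts moved more. At 8 h, leaving out any 1 array of the comparison took 38 genes to between 16 and 22. The count was 17 with an offset of 1, 18 without both arrays of high ACTB ratio, 64 with the array set as a block, 84 in the 8 h arrays alone, 520 with array weights and 10 at 2-fold. At 24 h, leaving out 1 array took 94 genes to between 48 and 206. The count was 184 with the array set as a block, 2 and 12 within the sets, 32 in the 24 h arrays alone and 9 at 2-fold.

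Dexamethasone on top of IFN-γ changed 55 genes at 8 h, or 22 to 51 with 1 array left out. The count was 32 with an offset of 1, 119 with an offset of 100, 143 with the array set as a block, 174 in the 8 h arrays alone, 734 with array weights and 11 at 2-fold. At 24 h it changed 1016, or 862 to 1018 with 1 array left out, 162 and 669 within the sets and 109 at 2-fold.

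The interaction at 8 h gave 0 genes, 0 to 2 with 1 array left out, 3 after quantile normalization, 4 with an offset of 100, 5 with a floor of 20, 3 with a trended and robust prior, 3 with the array set as a block, 4 in the 8 h arrays alone and 52 with array weights. At 24 h it gave 193, or 135 to 215 with 1 array left out, 331 with the array set as a block, 0 and 41 within the sets, 83 in the 24 h arrays alone and 47 at 2-fold.

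The replicate numbers did not pair the samples by the rule set in advance, but arrays of equal number were more alike at 24 h. Deviations from the group means correlated above 0.1 in 7 of 24 pairs of equal number at 8 h and 25 of 30 at 24 h. For pairs of unequal number it was 16 of 72 and 39 of 120. The mean correlation at 24 h was 0.22 for equal and -0.053 for unequal numbers, and 13 of 20 arrays matched their own number best. The 24 h array sets follow the numbers too, so number and set were not told apart there. A pairing at 24 h thus stays possible, and the main fit ignored it. With the number as a fixed replicate block the counts for dexamethasone were 78 at 8 h and 200 at 24 h, those on top of IFN-γ at 8 h 149, and the interactions 2 and 330. As a random replicate block they were 59, 169, 141, 3 and 305. The other counts changed by under 1.5 times with either block.

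The median effect of dexamethasone on IFN-γ-induced genes lay between -0.138 and -0.086 at 8 h and between -0.164 and -0.112 at 24 h with 1 array left out. It was -0.174 at 8 h and -0.306 at 24 h with genes chosen in the same arrays, and -0.293 at 24 h with genes chosen and measured in separate replicate numbers. At 8 h it was also -0.079 with array weights, -0.081 with an offset of 100 and -0.182 with an offset of 1. Between 67 and 89 of the 216 list tests were called over the settings run for lists, against 79, with 58 under an estimated correlation.

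Of 444 calls of named genes, 430 held after quantile normalization, 425 with an offset of 100, 422 without a filter and 372 under every leave-one-out fit. With an offset of 1, 356 of 427 held and 70 were lost. The interaction of SOCS1 at 24 h turned from -0.85 to 0.647 with that offset, without a call. Signal over background limits the dimmest genes, with 21.2% of all deposited values and 1.55% of those of the genes tested below 0. Genes with a group near the floor, such as MMP10, CXCL9 and SOCS1, have differences whose size follows the offset.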

Other observations

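The tests of NRF2 targets and of a loss of the whole IFN-γ response were chosen only after the results had been seen.

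Control cells differed between times, in a comparison that also differs in array set. Of 5503 genes 2256 differed between the 24 h and the 8 h controls, 1091 higher and 1165 lower. Cell cycle genes were higher in 29 of 31, with a list median of 1.32, and basal markers in 11 of 11, with a median of 0.83. Ribosomal protein genes were higher in 19 of 25 (median 0.53), and squamous genes lower in 16 and higher in 2 of 24 (median -0.76). The median log2 signal of the cell cycle list was 5.89 ± 0.02 (SD) in the 8 h controls, close to the floor of 5, and 7.50 ± 0.05 in the 24 h controls. With IFN-γ at 24 h it was 6.41 ± 0.17, below the 24 h controls but above the 8 h controls.

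NQO1, GCLC, AKR1C3 and ALDH3A1 were seen to fall with IFN-γ at 24 h, with AKR1C3 at -1.93 ± 0.14. The list of tryptophan, nitric oxide and oxidant enzymes had 4 genes higher and 5 lower of 13 and was not called. The fall of these 4 genes may reflect lower activity of NRF2, a transcription factor they share. In a list of other NRF2 targets, written without the 4, 13 of 19 genes tested fell and 1 rose, with a median of -0.63 (camera p = 0.000766, 0.0166 with an estimated correlation). This list was written after the results had been seen and holds CBR1 and GPX2, members of lists examined before. It is thus not fully independent of those results. The members that fell include AKR1B10 (-1.71 ± 0.18), GPX2 (-1.55 ± 0.11), TKT of the pentose phosphate pathway (-1.29 ± 0.12), the autophagy receptor SQSTM1 (-1.20 ± 0.14), GSR, which recycles glutathione (-0.89 ± 0.09), the cystine transporter SLC7A11 (-0.84 ± 0.20) and the ferritin light chain FTL (-0.67 ± 0.13). UGDH rose by 0.71 ± 0.14, while GSTP1, TXNRD1, TXN and PGD stood at -0.03, 0.10, 0.035 and 0.17 without a call. With dexamethasone added, the median of the NRF2 list was -0.094 without a call by camera, so the falls were not undone as those of cell cycle genes were. Because 1622 genes fell with IFN-γ at 24 h, with a median of -0.131 over all genes, a lower list is not specific to NRF2. NRF2 protein was not measured, and lower expression for another reason stays open.

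The fall of chemokines and inflammatory genes with added dexamethasone could come from a loss of the IFN-γ response as a whole. The median of the antiviral list fell by 4.02% of its log2 rise with IFN-γ at 24 h, where a loss of at least 25% had been asked for. Because that bound was written after the results had been seen, it cannot serve as a test. The GTPases stood at -0.465 with dexamethasone added, against an IFN-γ rise of 3.184, and the lymphocyte chemokines at -0.465 against 3.745. On the log2 scale these lists thus kept most of their median rise. CXCL9 and ICAM1 fell by less than 1 with dexamethasone added, while CCL5, CCL2 and CXCL8 fell by over 1. The IFN-γ rise of CXCL9 started at the floor, so the share of it that was kept follows the offset. What separates the genes that fell from those that did not was not tested.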
